A study of Arabidopsis thaliana with 6 samples.

How the data were processed

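Leaf RNA was measured on Affymetrix ATH1 arrays, 3 of wild type Col-0 and 3 of chr11-1 chr17-1, one sample per array, as the labels give it. The authors deposited log2 expression values per probe set, and RMA and Partek are named, per the submitters' processing notes, without versions, roles or order. Background, normalization and summarization settings are not given in the sources used here, and raw array images were not used here. The scale was checked on the values, which started at 2.96 and had array medians of 4.73 to 4.77. Values were used as deposited, with no further normalization.

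Of 22810 probe sets, 64 Affymetrix controls were left out and 22746 were tested, of which 1061 carry a suffix marking possible cross-hybridisation. Gene names came from the probe table given with the series and a gene table of the TAIR10.1 assembly, used for names and for which genes neighbour each other. The probe table lists 14016 probe sets, 13513 with 1 gene and 503 with several, and 8730 tested probe sets have no gene name here. Of the 13513, 13436 were found in the gene table and 77 were not. They cover 13356 genes, and 11933 of the probe sets have a gene with a locus code as its only name. Many well-known genes are therefore missing from the lists.

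Levels were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with 1 prior variance, two-sided), mutant minus wild type, with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of adjusted p 0.05. Fold changes of at least 2 were counted as well. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The random seed was 1.

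Before the data were examined, 24 gene lists with 355 entries, the tests, the alternatives and the rule for named genes were fixed. The rule names CHR11 and CHR17. It then takes the 10 largest rises and 10 largest falls past the threshold, with all 3 mutant arrays on 1 side of the wild-type arrays and 1 gene per probe set. From each list it takes up to 4 members past the threshold, or the 2 largest changes where none passes, and it always includes FT, SOC1, FUL, SEP3 and FLC. Other list members, the functions given for genes and the unnamed probe sets were added after their values were seen. Of the list entries, 52 were measured and named. The Polycomb group, SPL phase change, heat shock, morning clock and seed marker lists had 0, and the rule for transposable element genes found 0. List members were counted over all probe sets and adjusted over the list alone. Lists with 3 or more members were tested with camera with a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists; 11 planned lists had 1 or 2 members and 8 had 3 or more. A gene with several probe sets was represented by the one with the highest mean.

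Another 31 lists were made from gene symbols after the names were seen and before any expression value was tested. Of these, 2 are not reported here, though they count in the adjustment over the lists. The others are flower and fruit development, stomatal lineage, mitosis and DNA replication, meiosis, iron homeostasis, the UGT, CYP71B, TBL, SCPL, BGLU, GH9, expansin, XTH, TET, SWEET, GSTU, PUB, UBP, CML, GLR, RALFL, ATG8 and tubulin families, organelle RNA editing, IQD proteins, exocyst and SEC proteins, chloroplast-encoded and mitochondrion-encoded genes and annotated pseudogenes. From the iron list FRO1 and BTS were taken out on their names, after the value of FRO1 (0.16, not past the test) had been displayed. A further 3 lists came from general knowledge after the results above had been seen.

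The alternatives were quantile normalization, centring each array on its median, leaving out the lowest 30% of probe sets by mean, leaving out probe sets with a cross-hybridisation suffix, a trended robust prior, array weights, the replicate number as a block, leaving out each array in turn, a threshold of 0.01, and, for lists, the estimated correlation, fry and the mean of a gene's probe sets. The limma step was tested on simulated data with 200 of 22746 probe sets changed. It recovered 37.3% of changes of 0.5 on the log2 scale, 91.0% of changes of 1 and 97.0% of changes of 2, and 12 unchanged probe sets were called. In the data 28.6% of probe sets were called, a far larger share than was changed in the simulation. The adjustment is stricter when few probe sets change, so these recoveries do not carry over to the data. None of the 64 controls passed limma when fitted and adjusted with each other alone, apart from the main fit (lowest adjusted p = 0.178). Of these controls, 11 had an unadjusted p below 0.05, all of them higher in the mutant.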

Results

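RNA from leaves of 15-day Arabidopsis plants was measured on 6 single-colour ATH1 arrays, 3 of wild type Col-0 and 3 of the chr11-1 chr17-1 double mutant. CHR11 and CHR17 encode ISWI-type chromatin-remodelling ATPases. The deposited values are log2 expression levels per probe set; array medians lay between 4.73 and 4.77. Pearson's r across probe sets, which are not independent replicates, was 0.993 to 0.996 between arrays of the same genotype and 0.970 to 0.972 between genotypes. The first principal component, with 79.4% of the variance, separated the 3 mutant from the 3 wild-type arrays. The comparison asks which leaf transcripts differ in level between the double mutant and wild type, as the series title states. The labels do not say whether the 3 arrays of a genotype come from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

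CHR17, a targeted gene, had log2 levels of 4.57, 4.92 and 4.84 in the wild-type arrays and 5.33, 4.91 and 5.11 in the mutant arrays. The group means were 4.78 ± 0.18 and 5.12 ± 0.21 (SD, n = 3), a log2 difference of 0.34 (SE 0.13) that did not pass the limma test (Benjamini-Hochberg adjusted p = 0.0832, range over the alternatives 0.0406 to 0.265). Without mutant replicate 2 the difference was 0.44 and passed (limma adjusted p = 0.0406), and the 3 mutant arrays overlapped the wild-type arrays in level. The positions of the insertions and of the probes are not given in the sources used here, so this transcript does not check the labels. CHR11 has no named probe set here and was not analysed here.

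Leaves of the double mutant gave far more signal for AT3G28500, an acidic ribosomal protein P2 family gene, and for CHI (AT2G43570), a chitinase gene, than wild-type leaves. AT3G28500 rose 46.5-fold, from a log2 level of 4.52 ± 0.22 to 10.06 ± 0.09 (SD, n = 3), and CHI rose 13.8-fold, from 4.53 ± 0.04 to 8.32 ± 0.03. The largest fall of a named gene was that of AT3G16670, 91.4-fold, from 11.40 ± 0.10 to 4.88 ± 0.38. CHL, a chloroplast lipocalin gene, fell 15.1-fold, and the cold-regulated gene COR15B fell 12.4-fold. The autophagy gene ATG8B rose 7.33-fold and the leaf polarity gene YAB3 fell 2.97-fold.

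In all, 3178 of 22746 probe sets were higher and 3333 were lower in the mutant at a limma Benjamini-Hochberg adjusted p below 0.05, which is 28.6% of the probe sets tested. At least 2-fold changes were 623 rises and 518 falls. The median absolute log2 change among the 6511 was 0.59, and over all probe sets the median change was -0.0028. The 3 mutant arrays all lay on 1 side of the 3 wild-type arrays in 6428 of the 6511, and in 39.5% of all probe sets tested, against 10% by chance. Of 13356 genes with a name here, 1674 were higher and 1747 lower. The test found 1.70% of the lowest 30% of probe sets by level and 40.2% of the others. The wild-type levels of AT3G28500 and CHI lay below the array medians, and background was not measured, so such folds are of array signal and not of transcript amount.

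Among the 10 named genes with the largest rises, AT1G80130 rose 19.7-fold, AT5G39520 18.7-fold and AT3G45730 17.7-fold. The peroxidase gene AT2G37130 rose by 3.66 on the log2 scale, the lipid-transfer family gene AT3G53980 by 3.56, and the EF-hand calcium-binding gene AT3G47480 by 3.44. AT5G57785 and AT5G25470 rose by 3.33 and 3.28. Among the 10 largest falls, the copper amine oxidase gene AT1G31690 fell 24.8-fold, from 9.09 ± 0.07 to 4.46 ± 0.27 (SD, n = 3). AT2G43590, a chitinase family gene, fell 12.4-fold, so 2 chitinase family genes stood at opposite ends of the range. The phosphoethanolamine methyltransferase family gene AT1G73600 fell 10.1-fold and the fructokinase family gene AT1G66430 by a log2 change of -2.90. AT5G50100, AT4G22830 and AT5G56260 had changes of -3.06, -2.76 and -2.75. AT3G28500 had the smallest limma adjusted p (2.75e-09) along with CHI, and the largest adjusted p of these 20 genes was that of COR15B (1.29e-06). Of probe sets with no gene name here, the largest rises were 6.16 and 5.34 and the largest falls -3.96 and -3.65 on the log2 scale.

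**Figure D1:**
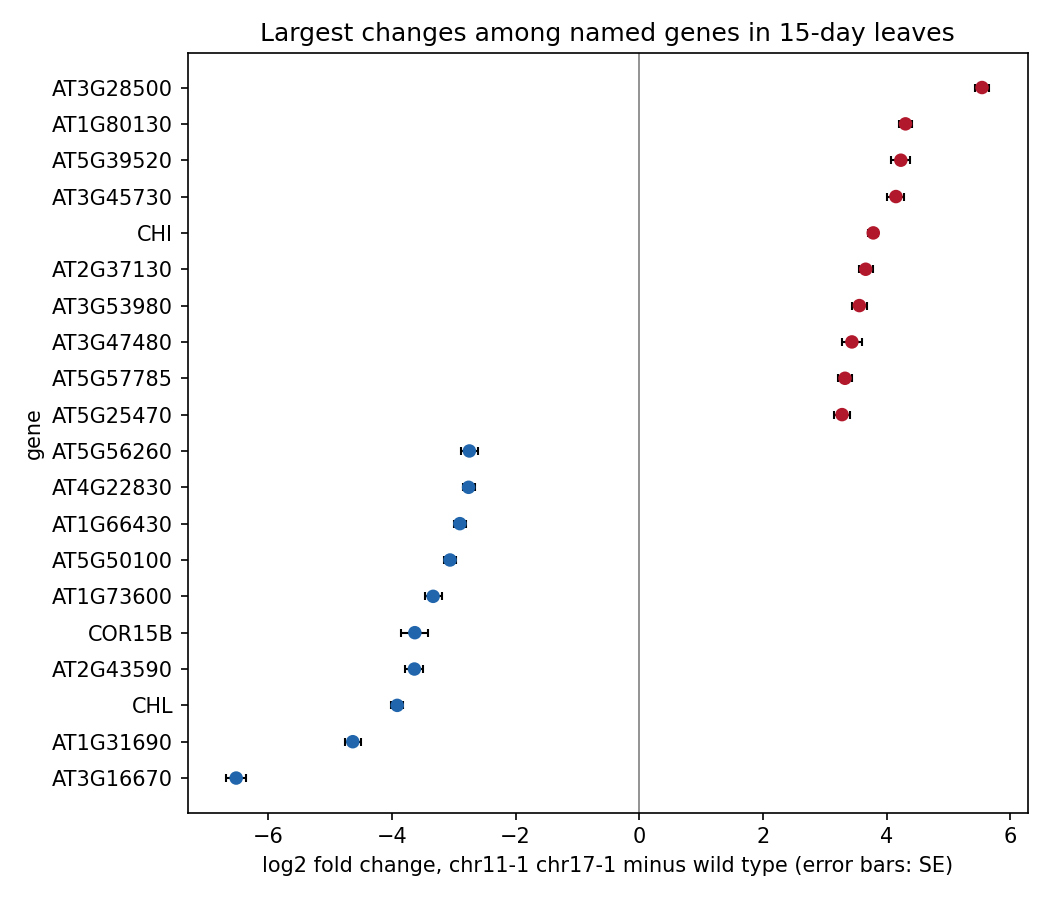
The log2 change, mutant minus wild type, is plotted on the horizontal axis with its SE for the 10 named genes with the largest rises and the 10 with the largest falls (3 arrays per genotype). AT3G28500 lies farthest right at 5.54 and AT3G16670 farthest left at -6.51.

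All 4 measured genes of the cold and ABA response list fell: COR15B (-3.63), COR15A (-2.60), COR47 (-1.64) and LTI30 (-0.46). These encode proteins that accumulate in cold or drought. COR15A went from 10.70 ± 0.10 to 8.10 ± 0.20 (SD, n = 3; limma adjusted p = 1.34e-07). Adjusted over the list alone, 4 fell. The list had a median of -2.12 and passed camera (adjusted p = 5.3e-05), which was lost when the correlation was estimated (adjusted p = 0.0819 with an estimated correlation). COR15B (AT2G42530) and COR15A (AT2G42540) are numbered neighbours and may not count as independent, and 4 of the 19 listed genes were measured.

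Of the 3 measured senescence genes, SAG29 (1.00) and WRKY6 (0.91) rose; WRKY53 had 0.23. SAG29 is a sugar transporter and the WRKYs are transcription factors, and none of the 3 is a chlorophyll breakdown enzyme. Adjusted over the list alone, 3 were higher. The list median was 0.91, with a camera adjusted p of 0.0296 (0.0157 to 0.0707 over the alternatives with the same test) and an adjusted p = 0.215 with an estimated correlation. The photosynthesis list had 1 rise, LHCB4.2 (0.54, limma adjusted p = 0.000747), and 6 of 7 members not past the test, with a median of 0.03 that became -0.01 after quantile normalization, -0.0078 without wild-type replicate 2 and -0.0052 without mutant replicate 1. All 7 lay at or above the 99.6th percentile of level, near the top of the array's range, and adjusted over the list alone 1 was higher. Its camera adjusted p was 0.592.

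In leaf development, YAB3 fell from 7.41 ± 0.17 to 5.84 ± 0.16 (SD, n = 3; limma adjusted p = 5.12e-06), while PHV, a leaf polarity gene, had 0.36 (adjusted p = 0.0566); adjusted over the list alone, 1 was higher and 1 lower. Both flowering repressors measured encode AP2-type factors: SNZ fell by 1.24 on the log2 scale (limma adjusted p = 5.03e-05) and SMZ had 0.40 (adjusted p = 0.0607), and adjusted over the list alone 1 was higher and 1 lower. Of 5 flowering promoters, AGL24 fell (-0.41, limma adjusted p = 0.014), and 4 did not pass: GI (-0.24), AGL19 (-0.07), AGL42 (-0.04) and FD (0.0022). AGL24 no longer passed without wild-type replicate 1 (-0.34, limma adjusted p = 0.0532) or without mutant replicate 3 (-0.33, limma adjusted p = 0.0533), in a range of 0.00933 to 0.0533 over its alternatives. Adjusted over the list alone, 1 promoter was lower. The promoter list had a median of -0.07 and a camera adjusted p of 0.483. UFO, the single floral identity gene measured, had a log2 difference of 0.0090. The wild-type levels of AGL19, AGL42, FD and UFO were low, 3.61, 3.56, 3.83 and 3.98 in that order, against array medians of 4.73 to 4.77. Genes this dim cannot show whether their transcripts were unchanged. FT, SOC1, FUL, SEP3 and FLC have no named probe set here and were not analysed here.

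GRX480, a glutaredoxin gene induced by salicylate, rose by 1.06 (limma adjusted p = 1.98e-05), and SAG101, a defence regulator, had -0.06; adjusted over the list alone 1 salicylate defence gene was higher. The jasmonate list had PDF1.2 at -0.13 and THI2.1 at 0.10, and neither passed limma, also when adjusted over the list alone; 0 had an unadjusted p below 0.05. All 3 auxin response genes changed, in both directions: WES1 (1.09) and GH3.3 (0.58) rose and IAA29 (-0.92) fell. WES1 and GH3.3 encode enzymes that join amino acids to auxin, and IAA29 a repressor of auxin responses. Adjusted over the list alone, 2 auxin genes were higher and 1 lower, with a list median of 0.58 and a camera adjusted p of 0.529. In aliphatic glucosinolate synthesis, BCAT4 rose (1.13) and AT2G31790, a glucosyltransferase gene, fell (-1.15), and both passed when adjusted over the list alone.

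The flavonoid enzyme gene DFR rose (0.39, limma adjusted p = 0.0321), while UF3GT (0.09) and AT4G14090 (-0.11) did not pass; adjusted over the list alone, 1 was higher. DFR no longer passed without wild-type replicate 2 (0.31, limma adjusted p = 0.132), wild-type replicate 3 (0.35, 0.111), mutant replicate 2 (0.34, 0.117) or mutant replicate 3 (0.38, 0.0815), with a range of 0.00721 to 0.132 over its alternatives. The list's median was 0.09, with a camera adjusted p of 0.592. Of 5 other chromatin remodellers, BSH, a SWI/SNF subunit gene, fell (-0.50, limma adjusted p = 0.00746), and INO80 (-0.20), CHB3 (-0.11), CHR23 (-0.07) and SWI3A (-0.03) did not pass. Adjusted over the list alone, 1 remodeller was lower, and the list had a camera adjusted p of 0.483. CHR17 was the single ISWI subunit measured, and adjusted over the list alone, which for 1 gene is the unadjusted p (0.0268), it was higher.

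None of 4 cell cycle genes passed limma, also when adjusted over the list alone, and 1 had an unadjusted p below 0.05: PRL, an MCM7 replication gene, had -0.50 (limma adjusted p = 0.0612), TOPII -0.23, AUR1 0.10 and AUR2 -0.09. PRL passed limma with all 6 arrays without dim probe sets (adjusted p = 0.0399), with a trended robust prior (0.0374) and with array weights (0.0355), and without mutant replicate 3 (-0.74, adjusted p = 0.000969); without mutant replicate 2 it had -0.33 (0.225), in a range of 0.000969 to 0.225 over its alternatives. The list had a median of -0.16 and a camera adjusted p of 0.548. The evening clock gene GI had -0.24 (limma adjusted p = 0.118), and adjusted over the list alone, again an unadjusted p, it was lower. No marker of other tissues passed limma, also when adjusted over each list alone, and 0 had an unadjusted p below 0.05. The root hair genes EXPA7 and EXPA18 had -0.09 and 0.03, the anther genes AMS and AT5G07230 -0.02 and -4.3e-05, and the meristem gene CLV3 -0.0067. Their wild-type levels were low, 4.05, 4.25, 3.74, 3.65 and 3.67 in that order, against array medians of 4.73 to 4.77. Markers this dim cannot show whether the samples of the genotypes held the same tissues. The signs of AMS, AT5G07230, CLV3, UFO and EXPA18 changed between the alternatives.

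**Figure D2:**
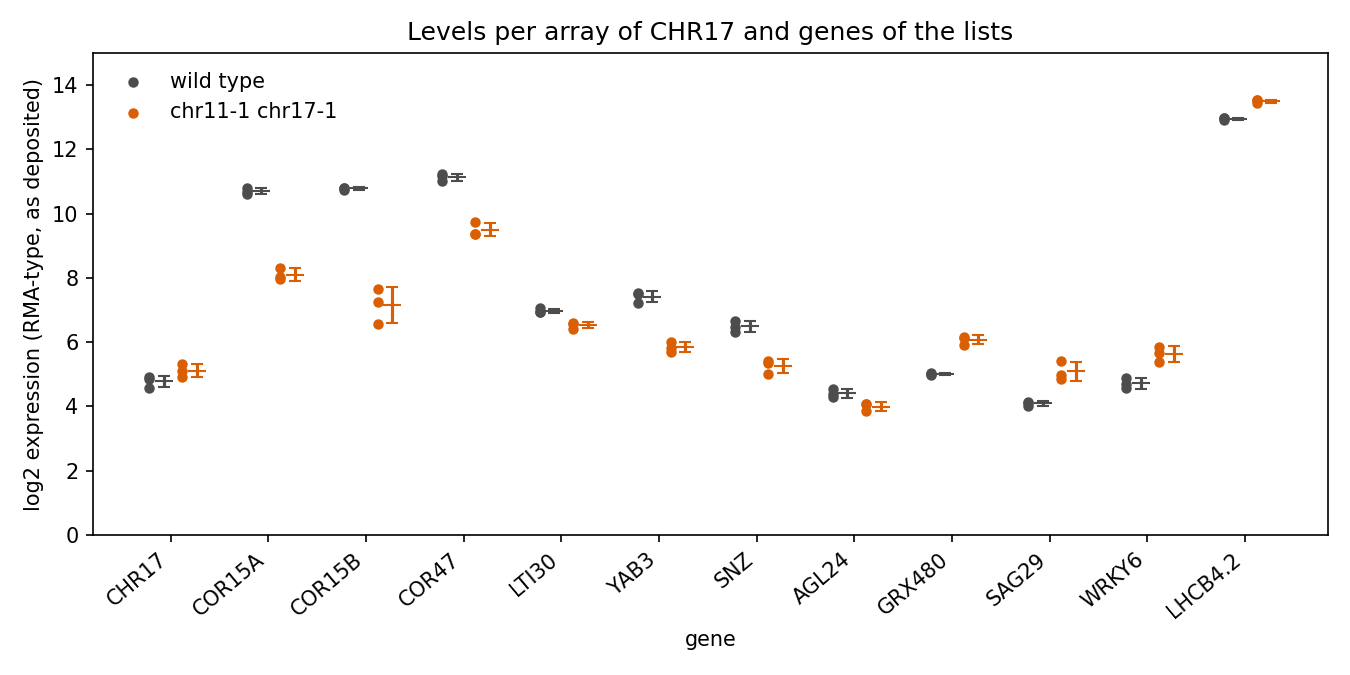
The log2 level of 12 genes is plotted on the vertical axis for each of the 6 arrays, as points with the mean and SD of the 3 arrays per genotype. COR15B goes from 10.79 ± 0.04 to 7.16 ± 0.56 and YAB3 from 7.41 ± 0.17 to 5.84 ± 0.16, while CHR17 overlaps between the genotypes.

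Of the 8 planned lists with at least 3 measured members, 2 passed camera, and 0 passed with an estimated correlation (lowest adjusted p = 0.0819 with an estimated correlation; 1 at an unadjusted p below 0.05). By fry, which tests whether genes of a list move one way and does not compare them with other genes, 3 passed. Among RNA quality readings, the 3' minus 5' log2 level of actin was 3.22 ± 0.06 in wild type and 3.02 ± 0.07 in the mutant (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays allow). For GAPDH it was 0.63 and 0.84 (exact p = 0.2), and for ubiquitin 1.12 and 1.08 (exact p = 0.6). A second set of actin controls read 11.98 (3') and 10.80 (5') in wild type and 12.13 and 10.83 in the mutant, a difference in the other direction. In the second GAPDH and ubiquitin sets the 3' level lay below the 5' level in both genotypes. These second sets were not tested, and the readings depend on the probe sets used. Of the 64 control probe sets, which include spiked-in RNAs and overlap in their targets, 56 had a level above that of wild type in the mutant, with a median log2 difference of 0.22. None passed limma fitted to the 64 controls alone, and the 11 with an unadjusted p below 0.05 were all higher, by 0.24 to 0.51. That fit has its own prior and adjustment, so it does not show whether controls would pass in the main fit. The GAPDH control AFFX-r2-At-GAPDH-3 had 0.47 (SE 0.10), close in size to LTI30 (-0.46, SE 0.09), which passed in the main fit. Values were not rescaled to the controls, so changes are relative to the bulk of probe sets. The 25S ribosomal RNA control read 8.90 in mutant replicate 1 and 10.85 in both other mutant arrays, against 10.49, 10.32 and 10.33 in wild type. Without that array 2937 probe sets were higher and 3395 lower, with at least 2-fold changes in 599 and 583.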

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

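The tests for strain segments were written after the largest changes had been seen and before their own values were computed, and the rule that a bound must be passed by more than its spread was applied after the values were seen. Named genes with changes of at least 2-fold could come from genome segments of another strain around the mutated genes. Of the 100 measured genes nearest to CHR11, 4% had such changes (exact Clopper-Pearson 95% interval 1.1% to 9.93%, permutation p = 0.645). Near CHR17 it was 5% (1.64% to 11.3%, permutation p = 0.431), against 4.37% over 13217 nuclear genes. All 5 were rises (2.31% over the genome, permutation p = 0.0778), while near CHR11 1% rose and 3% fell (2.06% over the genome, permutation p = 0.342). Both upper limits lie well above 4.37%, so a moderate local excess from genome segments of another strain around CHR11 and CHR17 stays open. Of the 577 genes with such changes over the genome, 4 lay among the 100 nearest to CHR11 and 5 among the 100 nearest to CHR17. These counts argue against segments of this span as the source of most of the 577 changes. For genome segments of another strain elsewhere in the genome, the highest count in 50 neighbouring measured genes was 8, the median of 10000 random placements (7 to 10 from the 5th to the 95th percentile, permutation p = 0.821), which met the bound set beforehand within its spread, and although 54.4% of 971 neighbouring pairs of changed genes had the same sign against 50.1% at random (permutation p = 0.0080), segments with few changed genes cannot be told apart from none. The excess of shared signs does not tell strain segments from other reasons for neighbours to move together, which were not tested. The difference between the genotypes as such was not tested apart from its strain background.

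Other splits of the 6 arrays into 3 and 3 number 10 with the real one, and 1 of the 10, the real one, gave as many probe sets past the limma test: 6511 against 0 in the highest other split. With 10 splits a share under 0.05 cannot be reached. Every other split also puts arrays of both genotypes into each group, so the genotype difference adds to the spread within groups. Few calls were therefore built into those splits, and their 0 is no reference for 6511.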

How the results depend on the processing

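All alternatives were planned, and tests on the added lists were chosen after the names were seen. The number of probe sets past the test lay between 5313 and 6893 in the settings at adjusted p 0.05, and all 4 counts of rises and falls stayed within 1.5 times their value, also at adjusted p 0.01 (2196 higher, 2276 lower). Between 80.0% and 99.98% of those of the 6511 still tested remained past the test in each of these settings, with 0 changes of sign. The replicate numbers do not pair the arrays (r of deviations from -0.30 to -0.17 for arrays with 1 number), and with the replicate block 5682 passed, DFR had an adjusted p of 0.0751 (0.00721 to 0.132 over its alternatives) and the tubulin list 0.0521 (0.0413 to 0.146 with the same test). Of 734 values for named genes under alternatives, 703 kept direction and side of the threshold, 5 passed there alone, 7 no longer passed and 19 changed sign. Most named genes were chosen for changes past the threshold in these same arrays, so much of this stability follows from the choice. Dim probe sets limit what can be seen: 1.70% of the lowest 30% passed.

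With an estimated correlation the cold and ABA list (-2.12) had an adjusted p of 0.0819 (1.7e-05 to 0.0819 over its alternatives) and the senescence list (0.91) 0.215. The senescence list had 0.0707 without dim probe sets (0.91), where fewer genes are compared; its range with the same test was 0.0157 to 0.0707. By fry, which asks another question, the photosynthesis list (0.034) had 0.0306 (range to 0.806). Changes of sign concerned values close to 0 as reported, and their cause was not tested. Under quantile normalization AT5G07230 had 0.0025, photosynthesis -0.015 and flower and fruit development -6.0e-05. With centred arrays AT5G07230 had 0.010 and CLV3 0.0035. Without dim probe sets, which leaves fewer members, CYP71B had -0.22, SCPL -0.076, GH9 -0.30, PUB -0.0064 and GLR -0.046. With array weights AMS had 0.020, AT5G07230 0.027, CLV3 0.037 and CYP71B -0.0088.

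Leaving out 1 array at a time gave CHR17 0.23 to 0.44, AMS -0.14 to 0.060, AT5G07230 -0.042 to 0.082, CLV3 -0.064 to 0.070, UFO -0.049 to 0.073 and EXPA18 -0.063 to 0.080. The list medians were -0.0078 to 0.078 for photosynthesis, -0.020 to 0.015 for CYP71B, -0.060 to 0.035 for GH9, -0.054 to 0.072 for PUB, -0.011 to 0.050 for SCPL, -0.032 to 0.031 for TET, -0.048 to 0.097 for XTH, -0.053 to 0.031 for flower and fruit development, -0.023 to 0.12 for mitochondrion-encoded genes and -0.027 to 0.0065 for pseudogenes. Among values that did not pass and kept their sign, PDF1.2 had -0.17 to -0.074, THI2.1 0.044 to 0.14 and TOPII -0.31 to -0.13, and the list medians were -0.25 to -0.030 for cell cycle, -0.11 to -0.022 for flowering promoters, 0.032 to 0.15 for flavonoids and -0.11 to -0.018 for iron homeostasis.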

Other observations

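Tests on the 3 lists from general knowledge were chosen after the main results had been seen and before their members' values were seen, and the photosynthesis bound was set after its values were seen. Of 9 ATG8 genes, which encode the ubiquitin-like proteins of autophagy membranes, 8 rose, among them ATG8B (2.87, 7.33-fold), ATG8E (1.44), APG8A (1.39) and ATG8C (1.14), and ATG8G had -0.25. Adjusted over the list alone, 8 rose; the median was 0.76 and the camera adjusted p 2.22e-05 (adjusted p = 0.579 with an estimated correlation). Of 7 tubulin genes 6 fell, among them TUB1 (-0.88), TUB9 (-0.78) and TUB7 (-0.71), and TUA1 rose (0.48); adjusted over the list alone the counts were the same. The tubulin median was -0.60 with a camera adjusted p of 0.0447 (adjusted p = 0.579 with an estimated correlation). It no longer passed without wild-type replicate 1 (0.0596) or 2 (0.0570), mutant replicate 2 (0.0721) or 3 (0.0593), or without dim probe sets (0.146), in a range of 0.0413 to 0.146 over the alternatives with the same test.

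Of the 31 added lists, 29 did not pass camera (adjusted p from 0.197 to 0.999), and 16 passed by fry. Among all 13356 named genes, 1674 rose and 1747 fell, so a list count near that share does not by itself set the list apart. The share called also depends on level: 1.70% of the lowest 30% of probe sets and 40.2% of the others passed. Median wild-type levels were 3.73 for pseudogenes and 7.08 for chloroplast-encoded genes, so lists of unlike level cannot be judged by 1 share. Of 24 mitosis and DNA replication genes 1 rose, SIM (1.19), a cell cycle inhibitor, and 4 fell, CKS (-1.49), BUB3.1 (-1.04), 3xHMG-box2 (-0.66) and POLD3 (-0.50). STOMAGEN, a peptide gene of the stomatal lineage list, fell (-1.15) and 3 of 4 did not pass. Of 36 flower and fruit development genes 3 rose and 4 fell, of 18 expansins 2 rose and 5 fell, and of 13 organelle RNA editing genes 4 fell. Among organelle genomes, 11 of 69 chloroplast-encoded genes rose, such as psbI (1.09), and 8 fell, such as rpl22 (-1.21), and 3 of 16 mitochondrion-encoded genes rose. Of 9 meiosis genes 0 passed limma, and 0 had an unadjusted p below 0.05, of 7 iron genes 1 rose, and of 989 pseudogenes 9 rose and 6 fell. The meiosis and pseudogene lists were dim, with median wild-type levels of 3.82 and 3.73 against array medians of 4.73 to 4.77. Their few calls cannot show that these transcripts were unchanged. In UGT, TBL, BGLU and SCPL lists 3, 4, 3 and 3 rose and 8, 1, 1 and 5 fell; in CYP71B, GH9, XTH and TET lists 3, 0, 2 and 4 rose and 5, 3, 1 and 3 fell. In SWEET, GSTU, PUB and UBP lists 4, 1, 2 and 1 rose and 1, 1, 2 and 3 fell; in CML, GLR, RALFL and IQD lists 2, 0, 2 and 1 rose and 2, 1, 2 and 4 fell, and of 8 exocyst and SEC genes 1 fell. When adjusted over the list alone, 4 exocyst and SEC genes were lower, 5 organelle RNA editing genes were lower, 3 expansins were higher and 5 lower, 2 mitochondrion-encoded genes were higher, and 3 pseudogenes were higher and 1 lower. In the CYP71B, SCPL, GH9 and GLR lists the median was above 0 and the test pointed down; their means were below 0 except that of CYP71B (0.05). Flower and fruit development had a median of 0.0035, a mean of -0.03 and a test pointing up, and iron homeostasis a median of -0.06, a mean of 0.0025 and a test pointing down.

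A first hypothesis is that GRX480 and CHI rose as part of a salicylate-type response. Of 26 genes listed as salicylate-inducible 12 were measured, 8 rose and 1 fell, with a median of 0.80 (camera adjusted p = 2.37e-06; adjusted p = 0.0195 with an estimated correlation). AT5G52760 (2.37), AT5G52750 (2.04) and AT3G18250 (1.73) rose most and AT5G55450 fell (-0.54); adjusted over the list alone 10 rose and 1 fell. AT5G52740, AT5G52750 and AT5G52760 are numbered neighbours and may not count as independent. The test is consistent with the hypothesis, but the list came from memory, and salicylate itself was not measured.

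A second hypothesis is that the COR15A, COR15B and COR47 falls belong to a broader fall of cold-regulated genes, which may extend to genes outside the planned list. Of 16 further genes listed 9 were measured, 4 fell and 1 rose, with a median of -0.27 that missed the bound of -0.3 (camera p = 0.0343, adjusted p = 0.0515; adjusted p = 0.139 with an estimated correlation). AT1G51090 (-2.48), AT5G62360 (-1.47), AT1G16850 (-1.09) and AT4G30650 (-0.58) fell and TIL rose (0.96); adjusted over the list alone 5 fell and 1 rose. The bound and the camera threshold were both met without wild-type replicate 3 (-0.30), mutant replicate 2 (-0.31) or mutant replicate 3 (-0.32), where limma's camera gave 0.0436, 0.0370 and 0.0386 before adjustment. Neither was met without mutant replicate 1 (-0.19), where it gave 0.0525. The outcome therefore rests on which arrays are used, and the hypothesis stays open.

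Another hypothesis is that the ATG8 rise reflects carbon starvation or leaf senescence, which could raise autophagy genes. Of 24 genes listed as induced by carbon starvation 7 were measured and 1 rose, AT3G15450 (0.67), with a median of 0.17 (camera adjusted p = 0.113; adjusted p = 0.250 with an estimated correlation; 82.3rd percentile of 10000 random lists). The share that rose met the bound set beforehand, under 25%, but within its spread (upper 95% limit 57.9%), so the explanation stays open. Without mutant replicate 3, 2 of 7 rose, with a median of 0.19, and limma's camera gave 0.0481 before adjustment. Without mutant replicate 1, 1 of 7 rose, with a median of 0.16, and camera gave 0.316 before adjustment. For senescence with loss of photosynthetic transcripts, the lowest 95% limit of the 7 photosynthesis genes was -0.42, above the bound of -0.5, which was itself set after these values were seen. LHCB4.2 rose from 12.95 to 13.50, but 5 of the 7 start higher than it did, and compression near the top of the range was not measured, so the explanation stays open. GI was the single clock gene measured, so a difference in harvest time between genotypes stays untested.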
